A study of Homo sapiens with 12 samples.

How the data were processed

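The study profiled K562 cells, a human erythroleukemia line with erythroid features, by chromatin immunoprecipitation and sequencing (ChIP-seq). Control cells and cells with a lentiviral short hairpin RNA against GATA1 or TAL1 were used. Per the labels' protocols, nuclei were digested with micrococcal nuclease, chromatin of the size of mono- or dinucleosomes was precipitated, and libraries were made with a commercial ChIP-seq kit. The series holds 12 libraries, never more than 1 per antibody and condition. GATA1, TAL1 and H3K27ac were profiled in all 3 conditions, LDB1 in control and TAL1 knockdown cells, and an unprecipitated input in control cells. Peak lists of 2 libraries were used, GATA1 and TAL1 in control cells. The other 10 libraries, among them every knockdown library and the input, were not analysed here, so no effect of either knockdown was measured.

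Each of the deposited lists gives a chromosome, a start and an end per peak in 3 columns with no header. They hold no height, fold enrichment, p-value, q-value or summit. Trimmomatic, Bowtie2, MACS2, deepTools and the human build hg19 are named, without versions or thresholds, per the submitters' processing notes. Whether peaks were called per library or on pooled reads is not given in the sources used here. The number of reads behind each library is not given in the sources used here either, so the depth of the libraries is unknown. All starts and ends lay within the hg19 chromosome lengths. Positions are given counted from 1.

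The lists shared their coordinates. Of the 7029 TAL1 peaks that overlapped a GATA1 peak by at least 1 bp, 7029 had the same start and the same end as the GATA1 peak. Both lists together made 24658 distinct intervals, none of which overlapped another, and the smallest gap was 37 bp within the GATA1 list, within the TAL1 list and across both. The smallest interval measured 85 bp in each list. A shared peak is therefore 1 interval present in both lists, and its width is not a separate measurement for each factor.

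The groups came from the sample titles. Overlap was computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and the count was checked with bedtools 2.31.1. Chance overlap came from 1000 random placements of the TAL1 peaks on their own chromosomes, and in an alternative within 1 Mb of their own positions. Assembly gaps were not masked. Widths were compared by a two-sided permutation test of the difference in medians with 100000 resamples. Chromosome lengths were those of GenomeInfoDb 1.38.1 and cytogenetic bands those of circlize 0.4.16, both for hg19 and with matching chromosome ends. Densities per arm leave out centromeric bands, variable heterochromatin and acrocentric stalks. The share of shared peaks was compared between each of 41 arms, or each of 133 bands with at least 50 GATA1 peaks, and the remaining peaks by Fisher's exact test (two-sided, scipy 1.17.1) with Benjamini-Hochberg adjustment at 0.05 within each family. Odds ratios within strata came from statsmodels 0.14.6, with percentile intervals from 10000 resamples of arms on each side, and figures from matplotlib 3.10.9. The TAL1 status of neighbouring GATA1 peaks was compared with 1000 permutations of that status over all GATA1 peaks. Intervals of either list with gaps of at most 12.5 kb were joined into clusters, and those of 3 or more intervals were counted and compared with 1000 random placements of all intervals. Intervals placed at random could overlap each other. For the share of shared peaks in clusters and alone, clusters were resampled 10000 times as units. Comparisons of shares and densities used chromosomes 1 to 22 and X.

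Each antibody has at most 1 library per condition, so no value has a replicate error. The p-values and exact (Clopper-Pearson) 95% intervals treat peaks as the units, with some exceptions. The units were arms for correlations across arms, sites where peaks were joined, and pairs for the intervals of neighbouring peaks. The p-values and intervals describe these lists, cover variation over these units only, and do not compare conditions. Neighbouring peaks are not independent, so arm and band tests were repeated with peaks within 2 kb joined to 1 site. In these tests a site counted as shared if it held peaks of both factors anywhere. Such a count can rise where peaks are dense. On simulated lists with 2000 planted shared peaks, the overlap count found 2042, against 52.2 on average for unrelated lists. The planted peaks were exact copies of GATA1 peaks, so at least 2000 had to be found. The simulation therefore shows only that the count ran as intended. With 10 bands planted at the overall share divided by 2, the band test recovered 42% of them and made 0.15 false calls per draw, over 20 draws. TAL1 status was drawn there for each peak on its own. Neighbouring peaks in the lists are not independent, so these rates do not carry over to them.

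Some alternatives were added after the data were seen, and they are named where the dependence on the processing is described. The design, the other alternatives and the rule for named items were fixed before the data were examined. That rule named the strongest peaks, which could not be ranked because the lists hold no strength, and the 5 clusters with most intervals, which are given. Arms, bands, peak-free stretches and the part of chromosome 22 that are named were chosen after their values were seen. The planned comparison of peak strength was replaced by one of interval width. The comparisons of clusters with random placement, of peaks in clusters and alone, of neighbouring peaks, of distances between the lists, of arms and of bands, and the correlations across arms, were added after the lists were examined. Motifs, positions relative to genes and gene lists were not tested, because no hg19 sequence or gene annotation was used here, and the gene table at hand follows GRCh38. For the same reason no peak is assigned to a gene.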

Results

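GATA1 and TAL1 binding was profiled by ChIP-seq in control K562 cells, with 1 library per factor. GATA1 is a zinc finger transcription factor required for erythroid and megakaryocytic differentiation. TAL1 is a basic helix-loop-helix factor that joins GATA1 in a complex with LMO2 and LDB1 on erythroid enhancers. The study asked how enhancers act on nearby erythroid genes and whether TAL1 is needed. The control lists analysed here bear on the starting point of that question, namely where each factor was found and how often both were found together.

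The GATA1 list held 22769 peaks and the TAL1 list 8918. GATA1 peaks covered 7.45 Mb, or 0.245% of chromosomes 1 to 22 and X, and TAL1 peaks covered 3.31 Mb, or 0.109%. The median width was 298 bp for GATA1 (interquartile range 192 to 427 bp) and 352 bp for TAL1 (246 to 470 bp). Neighbouring GATA1 peaks lay a median of 20.9 kb apart and neighbouring TAL1 peaks 68.3 kb apart. No GATA1 peak and 4 TAL1 peaks were on the mitochondrial sequence, and the comparisons below leave these out. The total number of reads per library is unknown, so the difference in peak number between the factors cannot be separated from a difference in depth or in antibody.

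Most TAL1 peaks were GATA1 peaks, while most GATA1 peaks were not TAL1 peaks. Of 8914 nuclear TAL1 peaks, 7029 (78.9%, 95% exact interval 78.0 to 79.7%) were also in the GATA1 list, and 1885 were in the TAL1 list alone. Those 7029 shared peaks made up 30.9% of the GATA1 list (30.3 to 31.5%), leaving 15740 peaks in the GATA1 list alone. With 8914 TAL1 peaks against 22769 GATA1 peaks, most GATA1 peaks had to be unshared at any degree of overlap. Depth is unknown, so the lower share does not show that GATA1 mostly bound without TAL1. Random placement of the TAL1 peaks on their own chromosomes gave 53.2 ± 7.18 overlaps (SD over 1000 placements), so the observed overlap was 132 times the random mean. Placement within 1 Mb of each peak gave 100.1 ± 9.70 overlaps and a ratio of 70.2. No placement under either scheme reached the observed number, and the permutation p of 0.001 was the smallest that they allowed. All shared peaks had identical boundaries in both lists, and no interval overlapped another in part. Random placement counted partial overlaps, which the lists do not hold. The ratios and p therefore compare unlike settings and do not measure how strongly the factors go together. The number shared also reflects how the intervals were defined before deposition.

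TAL1 peaks that were not GATA1 peaks often lay close to one. Among the 1885 TAL1-only peaks, 343 (18.2%, 16.5 to 20%) were within 1 kb of a GATA1 peak and 44.9% (42.6 to 47.2%) were within 10 kb. Random positions gave 1.89% and 11.2% (means of 100 placements). The median distance was 13.0 kb, against 155 kb for random positions. GATA1-only peaks lay farther from TAL1 peaks, at a median of 37.8 kb, against 252 kb for random positions. Of these, 5.25% were within 1 kb of a TAL1 peak, against 0.821% of random positions. Distances were not compared with placement within 1 Mb. How much of the closeness comes from both lists lying in the same peak-rich regions is therefore not known.

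Intervals in both lists were wider than intervals in 1 list. The median width was 373 bp for the 7029 shared peaks, 264 bp for the 15740 GATA1-only peaks and 274 bp for the 1885 TAL1-only peaks. The differences of 109 bp and 99 bp both had a two-sided permutation p of 1e-05, the smallest that the resamples allowed, and the same value after adjustment over both tests. If the common intervals were made by merging the peaks of both factors, shared intervals would be wider by construction, so these widths, and the shares by width below, describe the intervals as listed and not the binding of either factor. Among GATA1 peaks of 85 to 122 bp, the narrowest of 10 width classes of equal size, 10.4% (9.23 to 11.8%) were also TAL1 peaks. The share was 28.5% (26.6 to 30.4%) at 255 to 297 bp and 46.1% (44.1 to 48.1%) at 558 bp or more. Among TAL1 peaks, the share also in the GATA1 list was 57.0% (52.1 to 61.7%) in the narrowest class and 91.7% (89.9 to 93.2%) in the widest.

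**Figure D1:**
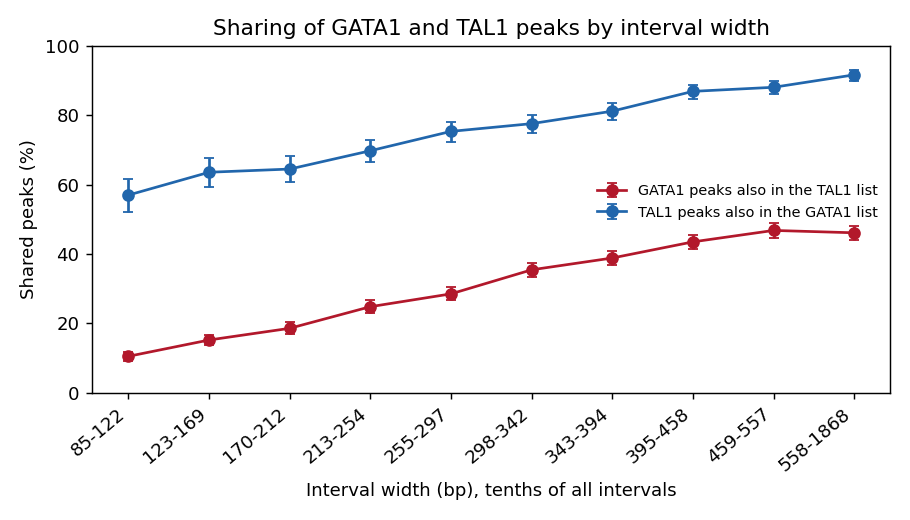
Share of GATA1 peaks also in the TAL1 list (red) and of TAL1 peaks also in the GATA1 list (blue), in percent, by interval width in bp, in 10 classes of all intervals; bars are exact 95% intervals over peaks. From the narrowest to the widest class the GATA1 share went from 10.4% to 46.1% and the TAL1 share from 57.0% to 91.7%.

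GATA1 peaks within a few kilobases of each other tended to be alike in TAL1 status. Where neighbouring GATA1 peaks were separated by at most 500 bp (2248 pairs), the second was a TAL1 peak in 74.3% of pairs (70.9 to 77.4%) if the first was, and in 14.7% (13.0 to 16.6%) if it was not. At gaps of 500 to 2000 bp the values were 48.8% and 28.5%, and from 2 kb to the distance used below to join clusters they were 36.8% and 30.8%. These 3 differences, of 59.5, 20.3 and 6.01 percentage points, each had an adjusted permutation p of 0.002 over 6 classes of distance. From that distance to 50 kb the shares were 29.9% and 28.3%, a difference of 1.64 points (adjusted permutation p = 0.21). The differences of 1.5 points at 50 to 200 kb and 3.27 points at 200 to 1000 kb did not pass the threshold either (adjusted permutation p = 0.3 and 0.21). The likeness was thus largest at gaps of at most 500 bp. Whether intervals this close are separate sites or parts of 1 enriched region cannot be told, because the lists give no height or summit.

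**Figure D2:**
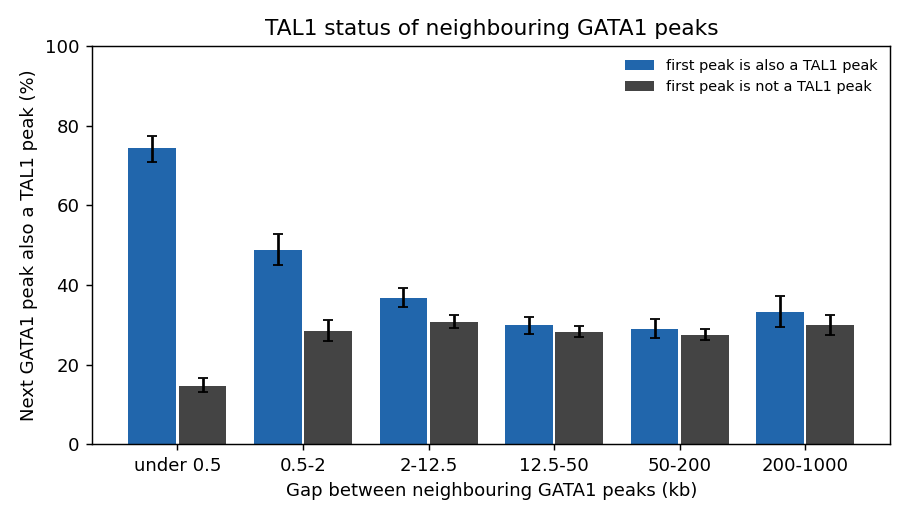
Percent of GATA1 peaks that were also TAL1 peaks, given that the preceding GATA1 peak was (blue) or was not (grey) a TAL1 peak, by the gap between them in kb; error bars are exact 95% intervals over pairs. The bars differ most at gaps under 0.5 kb (74.3% against 14.7%) and lie within 3.27 points of each other in the last 3 classes.

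Intervals lay in clusters more often than randomly placed ones. Joining intervals across gaps up to the distance fixed beforehand (given with the processing) gave 2328 clusters of 3 or more intervals, holding 9497 intervals, and 9117 intervals stood alone. Random placement of all intervals on their own chromosomes gave 312.0 ± 16.7 clusters (SD over 1000 placements), and placement within 1 Mb of each gave 856.3 ± 23.7. No placement gave as many clusters, and the two-sided permutation p of 0.002 was the smallest that they allowed. Both factors were present in 1723 of the clusters (74.0%), GATA1 without TAL1 in 605, and TAL1 without GATA1 in 0. TAL1-only intervals were few (1885, against 15740 GATA1-only and 7029 shared), so clusters of them alone would be rare in any case. These 3 counts were not compared with those from the make-up of the lists, so they do not show that the factors favour the same clusters. GATA1 peaks in clusters were TAL1 peaks in 34.4% of cases (33.4 to 35.4%), against 27.3% (26.3 to 28.2%) of those standing alone. Neighbouring peaks are not independent, so clusters were resampled as units, which gave a 95% interval of 5.59 to 8.61 points for the difference of 7.12 points. With peaks within 2 kb joined to 1 site and each site counted by its first GATA1 peak, the difference was 6.06 points (Fisher's exact test, two-sided p = 5.22e-15, over sites).

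The 5 clusters with most intervals were on chromosomes 3, 6, 7 and 11. The cluster at 6p25.2 (chromosome 6, 2903070 to 2999980) held 23 GATA1 and 5 TAL1 peaks, of which 4 were shared, within 96.9 kb. The cluster at 7q22.3 (chromosome 7, 106618868 to 106720204) held 24 GATA1 peaks, 8 of them also TAL1 peaks. At 6p22.2 (chromosome 6, 26285405 to 26352058) there were 19 GATA1 and 5 TAL1 peaks, with 4 shared. At 3p26.1 (chromosome 3, 5019199 to 5065383) there were 17 GATA1 and 6 TAL1 peaks, with 5 shared, within 46.2 kb. The cluster at 11p15.3 (chromosome 11, 12136173 to 12223230) held 18 GATA1 peaks, 7 of them also TAL1 peaks. Positions are those of hg19, and no gene is assigned to them.

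Peak density differed by chromosome arm for both factors. GATA1 peaks were densest on 19p (22 per Mb), 6p (20.9 per Mb) and 19q (18.3 per Mb). They were sparsest on 13q (1.87 per Mb), Xq (2.12 per Mb) and 9p (2.62 per Mb). TAL1 peaks were densest on 19p (9.50 per Mb), 19q (6.77 per Mb) and 17q (6.72 per Mb), and reached 6.18 per Mb on 6p. On 13q, Xq and 9p they numbered 1.03, 1.07 and 1.25 per Mb.

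The share of TAL1 peaks also in the GATA1 list differed from the rest of the genome on 6 of 41 arms (Fisher's exact test over peaks, Benjamini-Hochberg adjusted). By Fisher's exact test it was higher on 6p (88.7%, 85.0 to 91.8%, adjusted p = 2.97e-05), 1q (85.5%, 82.1 to 88.5%, adjusted p = 0.00195) and 7q (84.8%, 80.6 to 88.3%, adjusted p = 0.0312). By the same exact test it was lower on 13q (58.6%, 48.2 to 68.4%, adjusted p = 9.88e-05), 14q (69.0%, 61.8 to 75.5%, adjusted p = 0.0147) and Xq (66.7%, 56.5 to 75.8%, adjusted p = 0.0312). With peaks within 2 kb joined to 1 site, 2 arms passed, 6p (92.1%) and 13q (64.8%), against 81.8% of all sites with a TAL1 peak. A site counted as shared if both factors had a peak anywhere in it, which is likelier where GATA1 peaks are dense. Of the other arms, 14q had 72.9% (adjusted p = 0.0564 by Fisher's exact test), Xq 71.7%, 1q 86.6% and 7q 86.1%. Across the 41 arms the share was correlated with the GATA1 density on a log2 scale (Pearson r = 0.68, permutation p = 1e-05, adjusted 4e-05; Spearman rho = 0.58, permutation p = 0.00013, adjusted 0.00026). Without 13q and Xq, the arms farthest from the median density, r was 0.56. Single arms departed from this: the densest, 19p, had a share of 74.7%, and 16p (10.5 GATA1 peaks per Mb) 72.6%, while 5p (4.23 per Mb) and Xp (2.94 per Mb) had 82.9% and 81.7%. Shared peaks are counted in the GATA1 density as well as in the share, so part of the correlation is built in. Arms are parts of the same libraries, not replicates.

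The share of GATA1 peaks also in the TAL1 list was lower on 6p (26.2%, 23.8 to 28.8%, adjusted p = 0.00592 by Fisher's exact test) and higher on Xp (44.4%, 36.9 to 52.2%, adjusted p = 0.00592), and no other arm passed. With joined sites Xp alone passed (46.8%), and 6p had 30.4%, against 33.6% of all sites with a GATA1 peak (adjusted p = 0.242 by Fisher's exact test). Across arms the correlation with GATA1 density was r = -0.37 (permutation p = 0.016, adjusted 0.021) and rho = -0.30 (permutation p = 0.06, adjusted 0.06), of which the second did not pass. The number of GATA1 peaks is the denominator of this share and sets the density, so a negative correlation is partly built in. Of 133 bands, 6p22.1 (chromosome 6, 27000001 to 30400000) alone passed: 25 of its 153 GATA1 peaks (16.3%, 10.9 to 23.2%) were also TAL1 peaks (adjusted p = 0.00629 by Fisher's exact test). The band held 28 TAL1 peaks, so no more than 28 could be shared, and 25 of them (89.3%) were. TAL1 peaks numbered 8.24 per Mb there, against 2.94 per Mb over chromosomes 1 to 22 and X. The low share thus went with many GATA1 peaks and not with few TAL1 peaks. With joined sites no band passed.

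**Figure D3:**
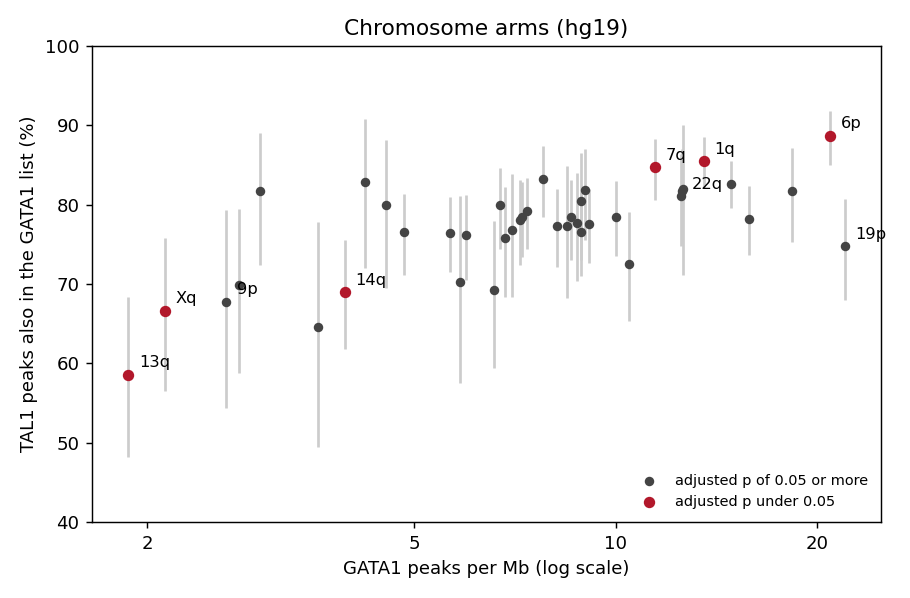
Each point is a chromosome arm: GATA1 peaks per Mb (log scale) against the percent of TAL1 peaks also in the GATA1 list, on an axis that starts at 40%, with exact 95% intervals over peaks. Arms with an adjusted p under 0.05 are red; 13q is lowest at 58.6% and 6p highest at 88.7%.

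The 3 chromosomes in the density plot were chosen after the values were seen, for the dense arm 6p, the sparse arm 9p and the uneven arm 22q.

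**Figure D4:**
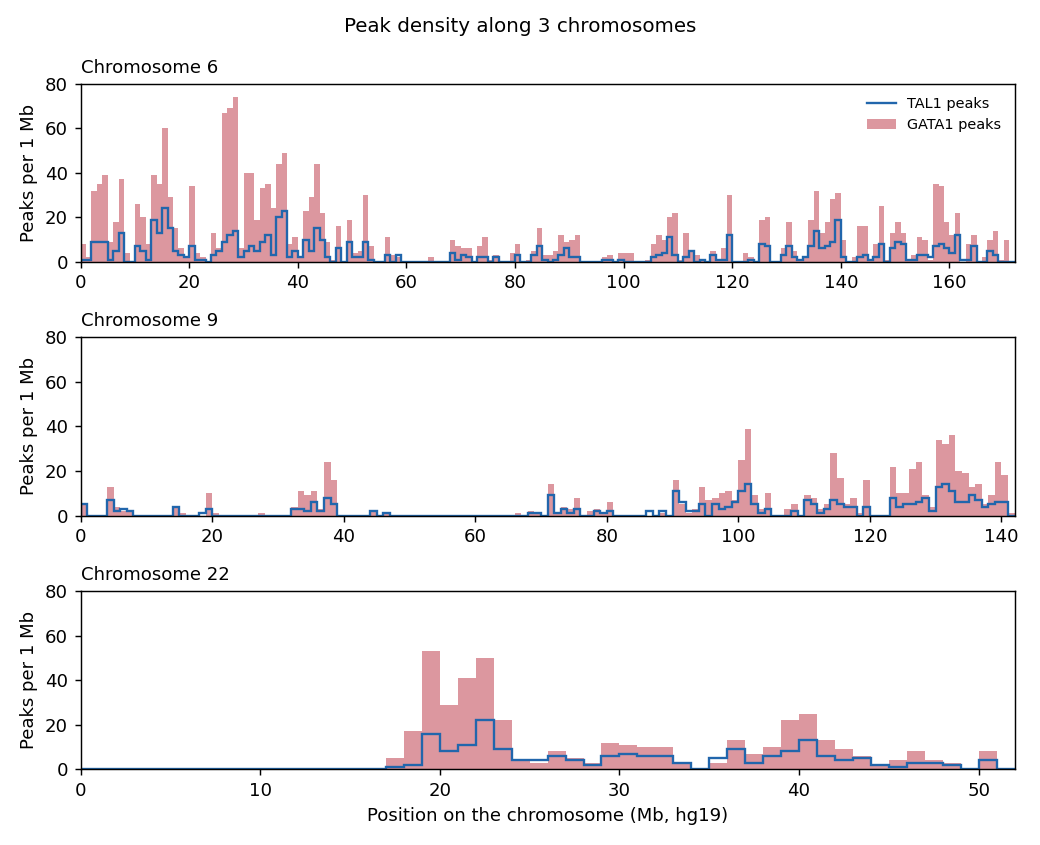
Number of GATA1 peaks (red bars) and TAL1 peaks (blue line) per 1 Mb window along chromosomes 6, 9 and 22 (hg19 position in Mb). GATA1 density was 20.9 per Mb on 6p and 2.62 per Mb on 9p, and on chromosome 22 most dense windows lay before 24 Mb.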

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

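The tests in this part were all chosen after the results were seen. The TAL1 list held 4 peaks on the mitochondrial sequence, which no comparison used, while the GATA1 list held 0. They lay at positions 1700 to 1892, 2987 to 3804, 14763 to 14918 and 14957 to 16543 of the hg19 mitochondrial sequence. They covered 16.6% of it, against 0.109% of chromosomes 1 to 22 and X in TAL1 peaks. A candidate explanation is background from the many copies of mitochondrial DNA in a cell, but the covered share only restates that 4 peaks lie on a short sequence and does not test it. It cannot be told apart from other sources, because the lists give no read numbers and the input library was not analysed here, and no biological explanation was tested.

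The second pattern is the identity of boundaries between the lists. Separate peak calling deposited unchanged was argued against, since 100% of overlapping peaks had the same start and end. The number of GATA1-only and TAL1-only neighbours closer than 37 bp, the smallest gap within a list, was 0, but this decides nothing, because the smallest gap over both lists was already known to be 37 bp. Whether both lists were drawn from a common set of intervals, made by a joint call, by merging or otherwise, stays open. No biological explanation was tested.

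The third pattern is that TAL1 peaks lay outside the GATA1 list more often on arms with few GATA1 peaks. On arms at or above the median GATA1 density 80.8% of TAL1 peaks were also GATA1 peaks, against 75.5% on the others, an odds ratio of 1.37, and a split by the density of GATA1-only peaks, to which shared peaks add nothing, put 0 arms on another side. The odds ratio within Giemsa classes was 1.35 (1.16 to 1.61 with arms resampled as units). With peaks within 2 kb joined to 1 site it was 1.37 (1.16 to 1.64), so Giemsa class did not account for the difference. Joining can raise the share where GATA1 peaks are dense, so the ratio for sites is not independent of the split. The share of TAL1 peaks also in the GATA1 list was 78.5% in unstained bands, 80.7% in the faintest stained and 76.0% in the darkest. Stratifying by class could therefore move the ratio little. Gene density itself was not measured, so gene-poor chromatin as a cause stays open. Narrower listed TAL1 intervals on the sparse arms were argued against as the whole cause. Median widths were 347 bp there and 355 bp on the dense arms. The odds ratio within 5 classes of width was 1.37 (1.18 to 1.62). Median widths hardly differed between the sides, so these classes could move the ratio little. Merging would widen shared intervals, so the width of TAL1 peaks on their own was not tested. Copy number in K562, a line with gained and lost chromosome segments, stays open, as does a biological difference between arms: on 22q density up to 24 Mb was 2.49 times that beyond it for TAL1 and 4.61 times for GATA1, but that boundary was chosen on these densities and copy number was not measured, so the ratios decide nothing.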

How the results depend on the processing

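The alternatives with joined sites, with widths as a filter and with permutations within width classes were added after the data were seen, as was the test of widths with a distance of 1000 bp. The share of TAL1 peaks also in the GATA1 list was 78.9% and was the same when at least 50% of each peak had to overlap, which identical boundaries guarantee; with centres within 200 bp it was 78.9%. With peaks within 1000 bp it was 82.7%, among intervals at least as wide as the median 85.3%, and among narrower ones 67.5%. The share of GATA1 peaks also in the TAL1 list was 34.5%, 42.2% and 19.4% in the same order, against 30.9%. Placement within 1 Mb lowered the ratio to random overlap from 132 to 70.2. Joining at 5 kb gave 1304 clusters of 3 or more intervals and at 25 kb 2869, against 2328. With peaks within 2 kb joined to 1 site, the arms that differed fell from 6 to 2 for TAL1 peaks and from 2 to 1 for GATA1 peaks, and the bands from 1 to 0 by Fisher's exact test, in which 16 bands had an unadjusted p under 0.05 before joining; the cause was not tested. With joined sites the correlation of GATA1 density across arms was 0.60 with the share of TAL1 peaks (permutation p = 0.0003) and -0.33 with that of GATA1 peaks (permutation p = 0.037). Leaving out the mitochondrial peaks gave 8914 TAL1 peaks. The difference in sharing between GATA1 peaks in clusters and alone was 7.12 points, 6.06 points by the first GATA1 peak of each joined site and 13.3 points with a TAL1 peak anywhere in the site, a count that larger sites raise by construction. In all, 14 alternatives stayed within the limits and 11 moved a value beyond them. The limits were a factor of 1.5 for counts and ratios, the 95% interval for shares, and the same direction and side of the threshold for tested values, so a tested difference such as the 13.3 points counts as within them whatever its size. No direction reversed. Thresholds by significance and lists of equal length were not run, because the lists hold no strength to rank peaks by. No paired analysis was possible because no antibody has more than 1 library per condition, and for the same reason no replicate was left out. Unknown depth limits every statement about peaks found in 1 list alone, since a site below the detection limit is not listed.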

Other observations

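The following regions were chosen after their values were seen. On 22q, 212 GATA1 peaks lay in the 6.1 Mb up to position 24 Mb (34.8 per Mb) and 206 in the 27.3 Mb beyond it (7.54 per Mb). TAL1 peaks numbered 11.1 and 4.47 per Mb in the same parts. Of the GATA1 peaks 28.8% were also TAL1 peaks up to 24 Mb and 45.1% beyond it, while of the TAL1 peaks 89.7% and 76.2% were also GATA1 peaks. On chromosome 6, 6p22.2, 6p22.1 and 6p21.33 held 40, 45 and 46.5 GATA1 peaks per Mb, and 7.78, 8.24 and 7.65 TAL1 peaks per Mb. Not all GATA1-dense bands of that arm were alike: 6p23 held 43.9 GATA1 and 18.9 TAL1 peaks per Mb, and 6p25.2 held 42.6 and 10. The most TAL1-rich tested bands by share were 8q22.1, where 26 of 54 GATA1 peaks were also TAL1 peaks (48.1%), and 16q24.1, with 30 of 66 (45.5%), neither of which passed adjustment (adjusted p = 0.193 and 0.294 by Fisher's exact test).

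Several long stretches held no peak of either factor outside centromeric and variable bands. The longest were 10.5 Mb from 5p14.3 to 5p13.3 (chromosome 5, 19019263 to 29567968) and 10.5 Mb from 13q31.1 to 13q31.3 (chromosome 13, 81174171 to 91669633). Others were 10.3 Mb on 4q, 10.3 Mb on Xq and 8.06 Mb on 18q. On 9p, 7.23 Mb from 9p24.1 to 9p22.3 (chromosome 9, 7166393 to 14395626) and 6.79 Mb from 9p21.3 to 9p21.2 (chromosome 9, 20692852 to 27482677) were free of peaks. Copy number was not measured, so stretches lost in K562 cannot be told from stretches without binding.

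By Giemsa class, GATA1 peak density was 10.5 per Mb in unstained bands, 12.4 per Mb in the faintest stained class, then 7.65 and 4.80 per Mb, and 2.68 per Mb in the darkest. The share of GATA1 peaks also in the TAL1 list was 30.7% (29.9 to 31.4%), 30.7% (29.0 to 32.5%), 32.9% (31.3 to 34.6%), 30.2% (28.2 to 32.3%) and 29.5% (27 to 32.0%) in the same classes, with no test between them. Centromeric bands held 73 GATA1 and 34 TAL1 peaks, with 24 shared.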
